A study of Mus musculus with 2 samples.

How the data were processed

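Trimethylation of lysine 4 of histone H3 (H3K4me3), a chromatin mark found at promoters, was mapped by ChIP-seq (sequencing of DNA bound to immunoprecipitated chromatin) in the lungs of mouse embryos at embryonic day 14.5. Per the labels, replicate 1 was made from the pooled lungs of 24 embryos and replicate 2 from those of 34. They are numbered as separate biological replicates of the same strain (B6NTac;B6NCrl/Lap), with the sexes mixed and with a size range of 300 to 500, for which the labels name no unit. The study therefore has 1 group of 2 replicates and no second condition, so the analysis describes where the mark lay and how far the replicates differed. An input control was not analysed here.

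The deposited files are 4 peak lists in mm10 coordinates. Per the deposited file descriptions, 1 list was called on each replicate's alignments, 1 on both replicates together (the pooled list), and the replicated list was derived from these 3. The aligner, the peak caller and the settings are not given in the sources used here, and neither is the rule behind the replicated list. The fold of each peak is the authors' value, a ratio of enrichment at the summit over a background. Within a peak list it was used to describe, rank or filter peaks and to compare gene lists. Between the replicates, folds were correlated and, at some genes, set side by side. The unit was checked on the values: with a background of 2.16 in replicate 1, 2.09 in replicate 2 and 4.26 in the pooled list, 52.0%, 51.4% and 51.0% of the folds lay within 0.005 of a whole step of (pileup + 1)/(background + 1), against 1% by chance. The −log10 p and −log10 q of each peak are also deposited by the authors. In the replicate lists 98.5% and 99.3% of the −log10 p values compared lay within 0.02 of the Poisson value of that pileup, and in the pooled list 0% did. The lowest deposited −log10 p was 2.05 in replicate 1 and 2.00 in replicate 2, so the lists hold weak peaks too. Read numbers were not analysed here, so the sequencing depth is unknown. The largest pileup implied by the folds was 243 in replicate 1 and 248 in replicate 2. Wilson intervals at 95% cover counting error only.

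Peaks were set against the protein-coding genes of GENCODE release M21 on the assembled chromosomes (21938 genes) and its genome sequence. None of the peaks passed the end of a chromosome of that genome, and 10 peaks of the replicated list lay on scaffolds. A gene was called marked when a peak of the replicated list lay within 1 kb of any of its annotated transcription start sites (TSSs). Peaks at most 1 kb apart were merged into domains. The width of a gene's promoter domain was that of the widest domain within 1 kb of any of its TSSs. Its promoter fold was the highest among the peaks there, so width and fold can come from different TSSs. Widths per replicate came from each replicate's own list and are given as mean ± SD with n = 2. Promoters were classed by CpG content: high with a 500 bp window within 700 bp of the TSS whose observed over expected CpG ratio was above 0.75 and whose GC content was above 55%, low with no window at 0.48 or more, and intermediate otherwise. All genes had a class. Peaks over 5 kb from every annotated TSS of any gene type were called distal.

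Before the data were examined, 27 gene lists were fixed: regulators and marker genes of the lung epithelium, mesenchyme and other cell types, housekeeping groups, signalling genes, Hox genes, imprinted genes and olfactory receptor genes as a negative control. Of the listed genes, 3 imprinted ones (H19, Meg3 and Kcnq1ot1) are not protein-coding in this annotation and were left out. Some genes stand in more than 1 list. The marked share of each list was compared with all other protein-coding genes by Fisher's exact test (two-sided), and its percentile was taken among 10000 random lists matched in 10 bins on the CpG ratio within 500 bp of the TSS. Median domain widths of the 23 lists with at least 5 marked members were compared with 100000 random lists of marked genes by a two-sided permutation test. Benjamini-Hochberg adjustment was made over all lists of a test, with a threshold of 0.05. The smallest p these permutations can give is 2e-05, and 0.0002 for the CpG-matched lists. Genes are not independent replicates, and those p-values describe the lists among genes of this tissue. Shares of peaks were compared with 100 shuffles of the peaks within chromosomes.

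The rule for genes named in the text was also fixed in advance: per list the 2 to 4 members with the widest domain, up to 4 members without a peak in alphabetical order, and a set of anchor genes of the lung and of other tissues; the coding genes with a TSS in the 20 widest domains; the 10 with the highest promoter fold; and the nearest coding gene of the 10 strongest distal peaks. The tests between pairs of lists, of promoter fold by list and of widths between the replicates were chosen after the data were seen, as were genes said to be so chosen. In the last, the log2 ratio of the widths in replicate 2 over replicate 1 was taken with 0.2 kb added to each width and compared with 100000 random lists matched on mean width.

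Alternatives were a stricter q threshold (the better-scoring 50% of each list), the pooled list, each replicate alone, other TSS windows (500 bp and 2 kb), a single TSS per gene, other merge gaps (none and 3 kb), a 10 kb limit for distal peaks, and 50% overlap of both peaks. Simulated lists held 20 of the 21938 genes. Of 100 random lists, 4% were called by the share test and 5% by the width test. Planted lists had 19 of 20 or 4 of 20 members marked, or widths multiplied by 2. For the CpG-matched test they were marked genes of CpG-poor promoters. In each case 100% were recovered, but weaker effects and shorter lists were not simulated, so the power for them is unknown. The share test also called 100% of lists drawn from CpG-rich promoters, and the CpG-matched test called 0% of such lists. Overlap counts were checked with bedtools 2.31.1 and differed by 0. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.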

Results

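H3K4me3 was profiled in embryonic mouse lung at day 14.5, a stage at which the airways are still branching, in 2 biological replicates of 1 group. The comparisons the design allows are between the replicates, and between groups of genes and regions within the tissue. Replicate 1 had 26754 peaks and replicate 2 had 29631, a mean of 28193 ± 2034 (SD, n = 2). They covered 35.3 and 38.8 Mb, with median widths of 1051 and 950 bp. The pooled list held 26428 peaks and the replicated list 22739 peaks with a median width of 1466 bp, covering 37.7 Mb or 1.38% of the assembled chromosomes.

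Most marked regions were found in both replicates. Of the replicate 1 peaks 88.2% (95% Wilson interval 87.8 to 88.6) overlapped a replicate 2 peak by at least 1 bp, against a mean of 3.15% after shuffling. Of the replicate 2 peaks 76.9% (76.4 to 77.4) overlapped a replicate 1 peak, against 2.82%. Across 23593 overlapping pairs, Spearman's rho was 0.830 for the fold and 0.757 for the width. Peaks found in a single replicate were weak and narrow: the 3151 of replicate 1 had a median fold of 3.17 and the 6843 of replicate 2 one of 3.23, and both sets had a median width of 255 bp. At the level of genes, 14513 protein-coding genes were marked in both replicates, 93 in replicate 1 alone and 260 in replicate 2 alone. Promoter domain widths had a rho of 0.913 across 14499 genes, and the median SD of a gene's width between replicates was 0.151 kb.

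The mark lay mainly at promoters, and above all at CpG-rich ones. Of the replicated peaks 73.2% (72.6 to 73.8) were within 1 kb of a TSS, against a mean of 10.4% and a maximum of 11.0% in 100 shuffles. A peak was found at 14604 of 21938 protein-coding genes, or 66.6% (65.9 to 67.2). The marked share was 98.6% (98.4 to 98.8) of the 11488 genes with high CpG promoters, 66.1% (64.7 to 67.5) of the 4172 intermediate ones and 8.20% (7.55 to 8.91) of the 6278 with low CpG promoters. High and low classes differed with an odds ratio of 808 (Fisher's exact test, two-sided, p at most 1e-300). Median domain widths were 2.41, 1.59 and 1.16 kb in the same order. With the stricter q threshold the shares were 88.8%, 34.4% and 1.58%.

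Regulators of the developing lung were marked throughout. A peak was present at 20 of 20 lung epithelial regulators, among them Nkx2-1, the transcription factor that specifies lung epithelium, Foxa2, the distal tip factor Sox9 and the airway factor Sox2. It was present at 25 of 25 lung mesenchyme regulators, among them Tbx4, Tbx5, Foxf1, Fgf10 and Wnt2, and at 30 of 30 branching signalling genes, among them Shh, its receptor gene Ptch1 and the Fgf10 receptor gene Fgfr2. The share among other protein-coding genes was 66.5%, and the adjusted p was 0.00139 for the epithelial regulators, 0.000292 for the mesenchyme regulators and 5.83e-05 for the branching genes (Fisher's exact test). Genes of the lung's structural cells followed. The mark was found at 21 of 21 endothelial genes (Kdr, Cdh5 and Pecam1 among them; exact test, adjusted p = 0.00104), 18 of 18 epithelial junction and keratin genes (0.00167), 12 of 12 smooth muscle genes (Acta2 among them; 0.0194) and 14 of 15 matrix and fibroblast genes, Lum being the exception (0.0440). Housekeeping groups were marked as fully: 20 of 20 ribosomal protein genes (exact test, adjusted p = 0.00139), 18 of 18 proteasome genes and 18 of 18 cell cycle genes (0.00167 each). The 23 anterior Hox genes (paralogues 1 to 8) were all marked (exact test, adjusted p = 0.000766). So were 18 of 19 forebrain and neuronal regulators (94.7%, interval 75.4 to 99.1, exact test, adjusted p = 0.0118), including Foxg1 and excepting Neurod6.

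Lists of 5 kinds were marked less often than other genes. Olfactory receptor genes, the negative control, had a peak at 3 of 1093 (0.274%, interval 0.0934 to 0.804, against 70.0% of other genes), and these were Olfr1033, Olfr658 and Olfr94, named after their values were seen; the replicates alone gave 0.0915 and 0.366%. Of the macrophage and leukocyte genes 1 of 15 was marked (exact test, adjusted p = 3.01e-05): Cd68 had a peak, while Ptprc, Adgre1, Aif1 and C1qa had none; replicate 2 alone had 3 of 15 (20%). Of the hepatocyte genes 1 of 13 was marked (Apoa1; exact test, adjusted p = 0.000118), with no peak at Alb or Afp. Germ cell genes had 3 of 14 marked (Dmrt1, Dazl and Tdrd1; exact test, adjusted p = 0.00167), and replicate 1 alone had 5 of 14 (35.7%). Airway cell genes had 6 of 18 marked (exact test, adjusted p = 0.00901), with peaks at the ciliated cell regulator Foxj1, at Ascl1 and at Cftr and none at the club cell secretory gene Scgb1a1. The other 10 lists did not pass the test. Alveolar cell genes had 11 of 16 marked, including Sftpc, the surfactant protein C gene, but not Sftpa1, Sftpb or Sftpd. Mesothelial genes had 7 of 10 (Wt1 among them), cartilage genes 12 of 13, peripheral neural and neural crest genes 11 of 14, posterior Hox genes (paralogues 9 to 13) 13 of 16 and imprinted genes 13 of 14 (exact test, adjusted p = 0.0670). Erythroid genes had 7 of 15 marked, cardiomyocyte genes 8 of 11, skeletal muscle genes 6 of 12 (Myod1 among them) and pluripotency genes 7 of 13, with no peak at Pou5f1. With the stricter q threshold, which left 11735 marked genes and 53.5% of other genes marked, endothelial (23.8%) and forebrain genes (0%) passed as lower, and the calls of epithelial junction (50%), smooth muscle (25%), anterior Hox (52.2%) and matrix genes (66.7%) ended. Of the lists that had not passed, posterior Hox (0%), erythroid (6.67%), pluripotency (7.69%), cardiomyocyte (9.09%), skeletal muscle (16.7%) and peripheral neural genes (21.4%) then passed as lower and imprinted genes (85.7%) as higher. Posterior Hox genes passed as higher with replicate 2 alone (100%) and with the pooled list (93.8%). The matrix call also ended with a TSS inside the peak (86.7%) or a single TSS per gene (86.7%), as did the endothelial call with the latter (85.7%), the smooth muscle (91.7%) and forebrain (78.9%) calls with the former, and the airway (33.3%), proteasome (66.7%) and anterior Hox (69.6%) calls without peaks shared between genes.

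**Figure D1:**
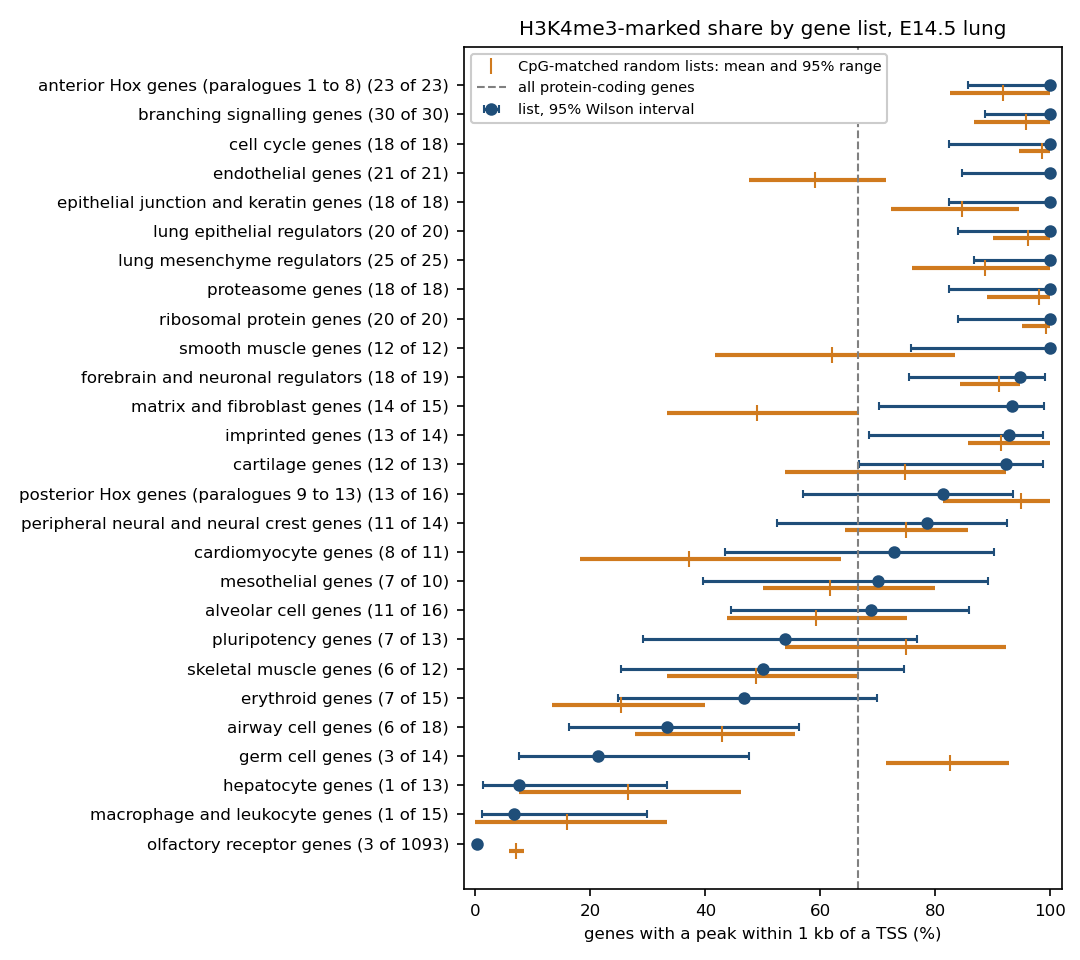
Share of each gene list with an H3K4me3 peak within 1 kb of a TSS (x axis, percent; blue points with 95% Wilson intervals), with the mean and 95% range of CpG-matched random lists in orange and the share of all protein-coding genes, 66.6%, as a dashed line. Endothelial genes sit at 100% above a matched mean of 59.1%, and germ cell genes at 21.4% below one of 82.5%.

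Since the CpG classes differed this much, each list was also compared with random lists of the same promoter CpG ratio. Markers of 4 cell types were above their matched lists by permutation: endothelial genes (100% against a mean of 59.1%), smooth muscle genes (100% against 62.1%), matrix and fibroblast genes (93.3% against 49.0%) and cardiomyocyte genes (72.7% against 37.2%). Their adjusted permutation p was 0.00135, 0.00324, 0.00135 and 0.0324, while cardiomyocyte genes had not passed the exact test against other genes (0.822). With a TSS inside the peak, cardiomyocyte genes passed that exact test as marked less often (27.3%, adjusted p = 0.0338). Germ cell genes (21.4% against 82.5%) and olfactory receptor genes (0.274% against 7.12%) lay below (permutation, adjusted p = 0.00135 each, from p = 0.0002, the smallest these lists can give). Lung epithelial regulators (96.1% in matched lists, percentile 80.5), forebrain regulators (91.0%, percentile 77.6) and peripheral neural genes (74.8%, percentile 69.4) did not pass this test. Of the lists marked more often than other genes, epithelial junction (permutation, adjusted p = 0.119), mesenchyme (0.140), anterior Hox (0.379), branching (0.729), ribosomal protein, proteasome and cell cycle genes did not pass it either. Nor did 3 lists marked less often: hepatocyte (7.69% against 26.5%), airway (33.3% against 42.9%) and macrophage genes (6.67% against 15.96%; permutation, adjusted p = 0.307, 0.570 and 0.729). The cardiomyocyte call ended without replicate 2 (percentile 98.5), where fewer of its genes had a peak (7 of 11, against 10 in replicate 2 alone). Erythroid genes (46.7% against 25.3%; permutation, adjusted p = 0.0710) passed in that setting as above their matched lists (percentile 99.9). With the stricter q threshold the percentiles of smooth muscle, endothelial and cardiomyocyte genes were 5.06, 0.510 and 13.1, and endothelial genes then passed as below their matched lists (permutation, adjusted p = 0.0457). Mesenchyme regulators passed there as above their matched lists (percentile 99.985, permutation, adjusted p = 0.0027).

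Regulators of lung development had wide promoter domains. The median domain of the 20 lung epithelial regulators was 8.37 kb (replicate medians 8.30 ± 0.204, SD, n = 2), 3.74 times the 2.24 kb of all marked genes. At Nkx2-1 the domain was 20.2 kb wide (20.2 ± 0.291 in the replicates), from 56518294 to 56538505 of chromosome 12, and covered the whole gene (56531958 to 56536908). Foxa2 had 14.1 kb (14.3 ± 0.473), Foxa1 14.1 kb (14.0 ± 0.0537), Irx2 12.6 kb, Sox9 5.92 kb and Sox2 5.91 kb. The 25 mesenchyme regulators had a median of 5.30 kb (6.08 ± 0.868), with 18.5 kb at Ptch1 (18.4 ± 0.101), 17.7 kb at Tbx5 (17.3 ± 0.00707), 12.9 kb at Foxf1 (15.9 ± 3.29) and 11.2 kb at Tbx4 (11.1 ± 0.111). The 30 branching signalling genes had a median of 5.84 kb (5.86 ± 0.261), with 10.4 kb at Shh, 8.97 kb at Fgfr2 and 5.11 kb at Fgf10. Each of these 3 lists had p = 2e-05 in the permutation test, the smallest it can give (adjusted p = 0.000115). The lists are not separate evidence, since the branching list shares members with the others. Shh and Fgfr2 also stand in the epithelial list, and Ptch1 and Fgf10 in the mesenchyme list. Domains were also wider at imprinted genes (4.55 kb, led by Gnas at 9.67 kb and Igf2 at 7.31 kb; permutation, adjusted p = 0.000184), matrix genes (3.64 kb, Col3a1 5.10 kb; 0.00383), smooth muscle genes (3.30 kb; 0.0225), cell cycle genes (3.23 kb; 0.0135), ribosomal protein genes (3.03 kb; 0.0225) and endothelial genes (2.95 kb, Egfl7 6.87 kb and Kdr 4.23 kb; 0.0389).

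Domains were narrower at skeletal muscle genes (1.08 kb, adjusted p = 0.0135), cardiomyocyte genes (1.28 kb, 0.0206) and pluripotency genes (1.19 kb, 0.0210) by the same permutation test. Forebrain regulators, nearly all marked, had a median of 2.17 kb, close to that of all marked genes (permutation, adjusted p = 0.833; Foxg1 2.90 kb), but they passed as narrower when matched on CpGs (ratio 0.642, permutation, adjusted p = 0.00213) and had a ratio of 1.35 with a 3 kb merge gap. The difference itself was tested after these values were seen: lung epithelial regulators were 6.21 kb and lung mesenchyme regulators 3.13 kb wider than forebrain regulators (permutation test, adjusted p = 4e-05 each), and epithelial regulators 5.72 kb wider than the epithelial junction and keratin genes (adjusted p = 0.000107). These pair tests were not matched on CpGs. Random lists so matched had medians of 3.35 kb for the epithelial, 2.81 kb for the mesenchyme and 3.37 kb for the forebrain regulators. For the junction and keratin genes the matched median was 2.47 kb. Medians that did not pass were 2.96 kb for erythroid, 2.71 kb for alveolar (Sftpc 5.86 kb), 2.65 kb for epithelial junction (Esrp1 4.86 kb), 2.33 kb for proteasome, 2.25 kb for mesothelial (Wt1 3.86 kb), 2.06 kb for peripheral neural, 1.75 kb for airway (Foxj1 2.45 kb) and 1.67 kb for cartilage genes. The erythroid median depended on the replicate: its ratio to all marked genes was 1.84 and passed without replicate 2, and was 0.801 without replicate 1. The smooth muscle and endothelial calls ended without replicate 2 (ratios to all marked genes 1.37 and 1.29) and with a 3 kb merge gap (1.43 and 1.31), without a merge gap smooth muscle turned to 0.847 and endothelial genes had 1.15, and the ribosomal call ended when matched on CpGs (1.23) or with the stricter q threshold (1.19), as did the endothelial call with the latter (1.5). All 3 calls of narrower lists ended without replicate 1 (cardiomyocyte 0.713, skeletal muscle 0.918 and pluripotency 0.660); that of skeletal muscle also ended without replicate 2 (0.567) and with the pooled list (0.621), and that of cardiomyocyte genes with a 3 kb gap (0.753).

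**Figure D2:**
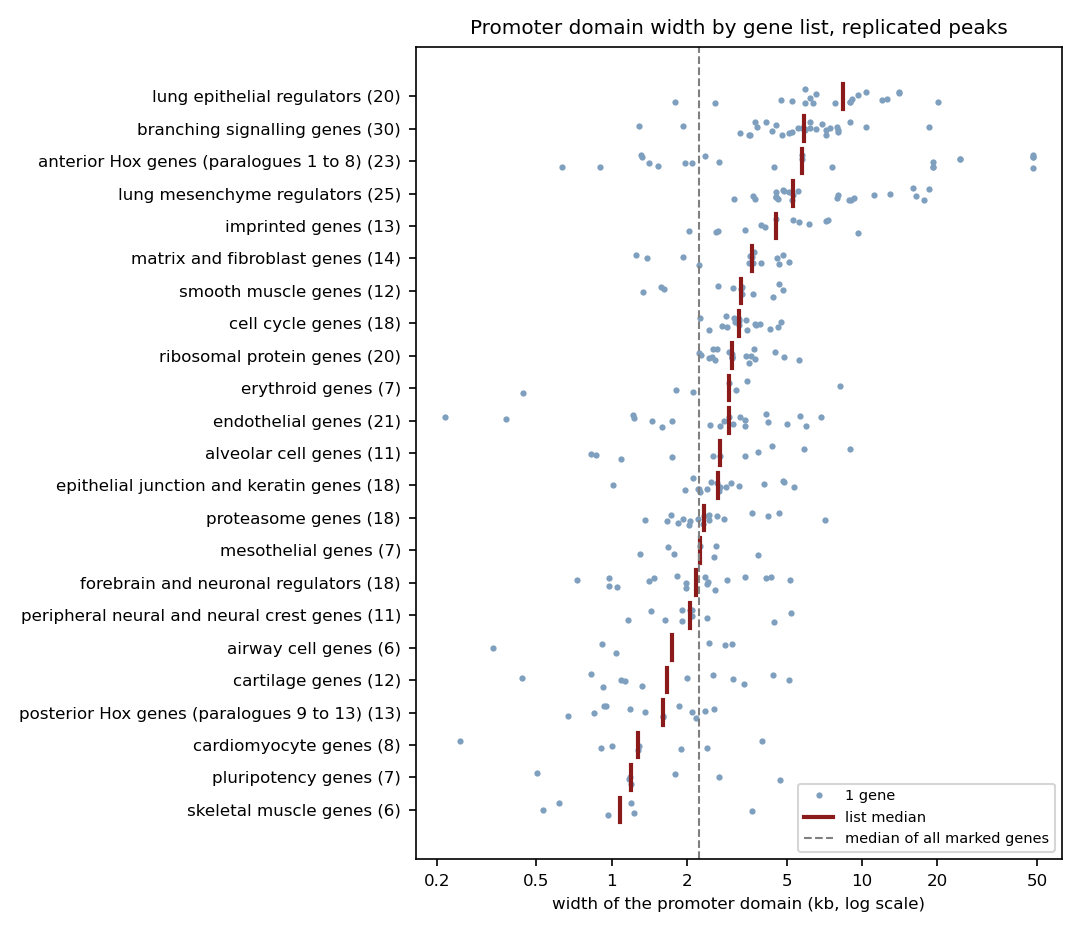
Width of the promoter domain (x axis, kb, log scale) of each marked gene in 23 gene lists, with the number of marked members in brackets, the list median as a red bar and the median of all marked genes, 2.24 kb, as a dashed line. Lung epithelial regulators have the highest median, 8.37 kb, and skeletal muscle genes the lowest, 1.08 kb.

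Width and height of the mark ranked the lists differently. The median promoter fold, the authors' value, was 48.1 over all marked genes. It was higher at ribosomal protein genes (65.5, adjusted p = 0.00342), proteasome genes (62.9, 0.0194) and cell cycle genes (61.9, 0.0331) by a permutation test added after the data were seen. It was lower in 12 lists, among them endothelial (15.5), forebrain (14.4), posterior Hox (6.09) and cardiomyocyte genes (5.28). Lung epithelial (35.9) and mesenchyme regulators (37.3) did not pass that permutation test (adjusted p = 0.119 and 0.129). Among single genes, Pfn1, an actin-binding protein gene, and its neighbour Eno3 shared the peak with the highest fold, 91.5, in a domain of 11.3 kb, followed by Clptm1 and Phrf1 (90.3 each), Ywhaz (89.6), Kdm2a (89.4), Dhx9 (89.2), Rnf114 and Spata2 (88.4 each, a shared peak) and Dpm1 (88.3, tied with 4 further genes).

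In the Hoxa and Hoxb clusters wide domains lay over anterior genes. The widest domain of all, 48.0 kb from 96298762 to 96346801 of chromosome 11, held a TSS of each of Hoxb3, Hoxb4, Hoxb5 and Hoxb6. It measured 31.7 kb in replicate 1 and 48.3 kb in replicate 2. A domain of 24.7 kb on chromosome 6 (52156617 to 52181353; 24.5 ± 0.211 in the replicates) held Hoxa1 and Hoxa2, and one of 19.2 kb (52194815 to 52214052) held Hoxa3, Hoxa5 and Hoxa6. The anterior genes had a median of 5.78 kb (p = 2e-05, the smallest the permutation test can give), and the posterior genes, which pattern the hind trunk and limbs, one of 1.61 kb (adjusted p = 0.0605), led by Hoxa10 with 2.56 kb and Hoxa9 with 2.35 kb. The posterior genes passed as narrower without replicate 2 (ratio to all marked genes 0.527), without a merge gap (0.504) and matched on CpGs (0.4997). The difference of 4.18 kb had an adjusted p of 0.00124 in a permutation test added after the values were seen, which counted a shared domain once for each gene. Because neighbouring anterior genes share domains, 23 genes made 16 domains, and counting each domain once the anterior median was 2.23 kb and no longer passed (ratio 1.03). The posterior median stayed at 1.61 kb, and the difference was not tested with each domain counted once. Within the Hoxa and Hoxb clusters Hoxa7 had 2.68 kb and Hoxb1 1.33 kb, both named after their values were seen. The anterior genes of the other clusters, named after their values were seen, had 2.37 kb at Hoxc4, 2.09 kb at Hoxc5, 1.96 kb at Hoxc6, 1.53 kb at Hoxd8, 1.41 kb at Hoxd1, 1.31 kb at Hoxd3, 0.895 kb at Hoxd4 and 0.633 kb at Hoxc8. Hoxc11, Hoxc12 and Hoxd12 had no replicated peak. Posterior Hox genes were wider in replicate 2 (median log2 ratio 1.05 over 16 genes, adjusted p = 0.00016, permutation test), where all 16 had a peak against 13 in replicate 1.

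**Figure D3:**
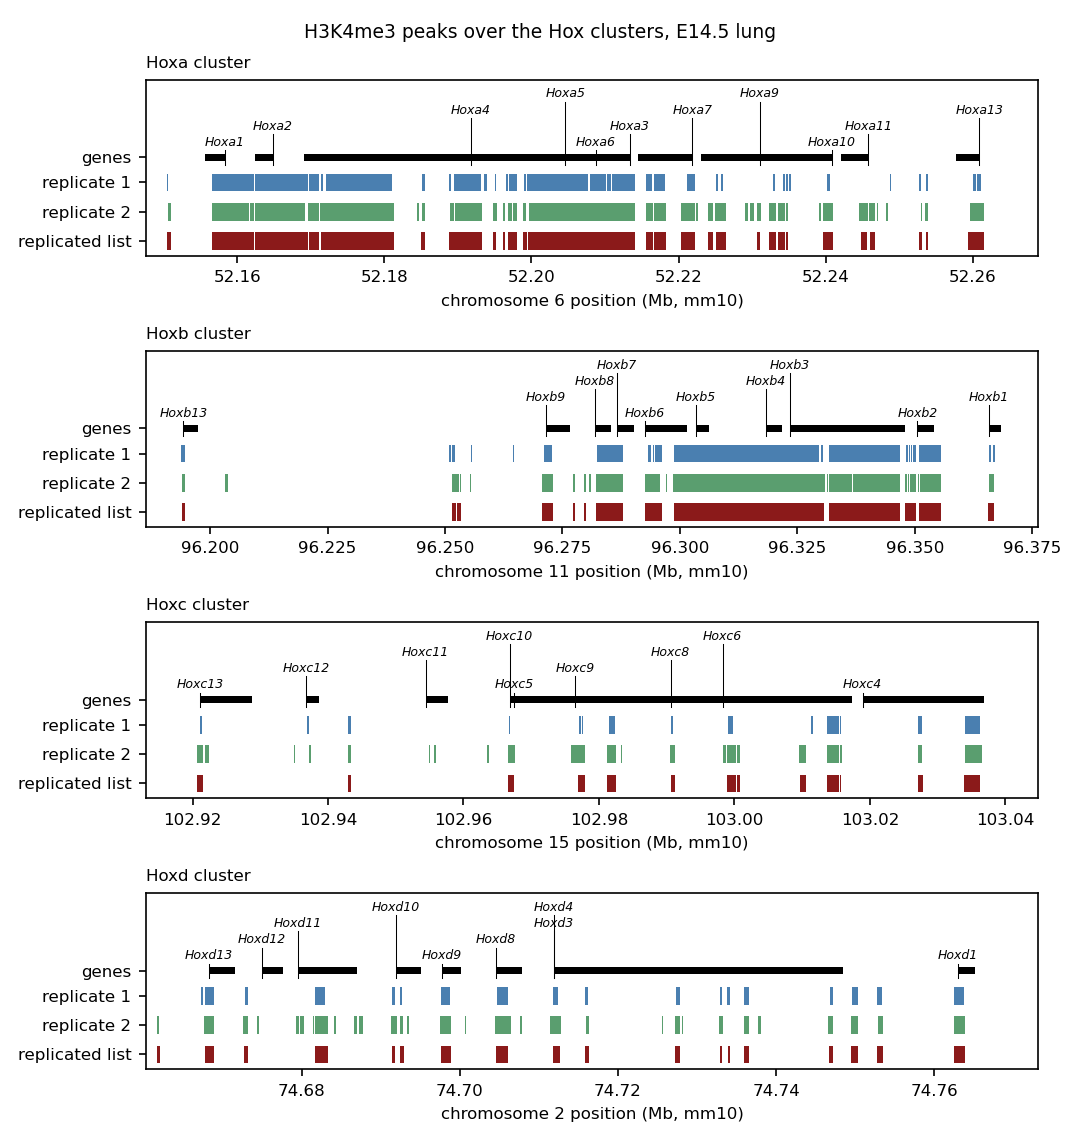
Peaks over the Hoxa, Hoxb, Hoxc and Hoxd clusters (x axis, mm10 position in Mb) in replicate 1, replicate 2 and the replicated list, with gene bodies in black and a thin line at the 5′ end of each gene. Near-continuous blocks span Hoxb3 to Hoxb5 and Hoxa1 to Hoxa2, while peaks over the genes of paralogues 9 to 13 and the anterior Hoxd genes are short.

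Further domains among the 20 widest lay outside the Hox clusters. After the Hoxb block came Nr2f2, an orphan nuclear receptor gene, with 25.5 kb (25.2 ± 0.243, SD, n = 2). Nfib, a factor of lung maturation, had 18.2 kb (17.9 ± 0.419), Zeb2 16.7 kb, Tbx2 16.4 kb and Tbx3 15.9 kb. Irx5 and Meis1 had 14.9 kb each and Zfp503 14.5 kb. The 20 widest also held the chromatin regulators Kdm6b (13.7 kb) and Setd1b (13.8 kb, with Rhof), Tnrc18 (13.02 kb) and Smad7, an inhibitor of TGF-beta signalling, with 13.01 kb (11.4 ± 2.54). With a 3 kb merge gap 12 of the 20 stayed among the 20 widest, and 18 and 17 did with replicate 2 or replicate 1 alone.

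Away from annotated TSSs the mark was sparse and weak. Distal peaks numbered 3330, or 14.6% (14.2 to 15.1) of the replicated list, with a median fold of 5.80 and a median width of 613 bp, against 38.8 and 1862 bp at promoters. Of those on assembled chromosomes 61.2% were intergenic, 30.3% intronic and 8.47% exonic, and 2953 of 3328 (88.7%) overlapped a peak in both replicates. The strongest, with a fold of 78.2, was 5.02 kb wide on chromosome 15 (85669524 to 85674545), in an intron of the long non-coding RNA gene Lncppara and 60.4 kb from the nearest coding TSS, that of Ppara. The next were intergenic, 18.7 kb from Fcgr4 (fold 61.6), 81.8 kb from Arhgap32 (60.0), 72.1 kb from Tln2 (59.0) and 17.9 kb from Wnt11 (54.7). A peak 39.3 kb from the Tns3 TSS lay in an intron of that gene (54.2), and a peak nearest Cluh in an exon of Ccdc92b (52.3). The rest of the 10 were nearest Cdk12 (52.4), 9230112D13Rik (52.1) and Adgrl1 (50.6). With the stricter q threshold 206 distal peaks were left (1.81%), and replicate 2 alone had 5062.

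Markers of heart muscle and of red blood cells differed between the replicates in opposite directions. Over the 14866 genes marked in either replicate, the median log2 width ratio of replicate 2 over replicate 1 was 0.09. Cardiomyocyte genes had a median of 2.15 (95% range of width-matched lists −0.03 to 0.34) and were wider in replicate 2 at 10 of 10 genes: Nkx2-5 measured 0.737 kb in replicate 1 and 4.83 kb in replicate 2, Actc1 0.796 and 4.32 kb, and Myh6, Myh7 and Myl2 had a peak in replicate 2 only. Erythroid genes had a median of −1.89 (range −0.05 to 0.30) and were wider in replicate 1 at 8 of 8: Gypa measured 5.55 and 1.11 kb, Slc4a1 4.50 and 0.486 kb, and Gata1, the master erythroid factor, and Alas2 had a peak in replicate 1 only (Myh6 and Alas2 were named after their values were seen). The adjusted p was 0.00016 for both lists by permutation. Of the 24 lists compared, 6 passed: beside these 2 lists, posterior Hox (1.05, adjusted p = 0.00016), skeletal muscle (1.04, 0.00036), mesothelial (0.38, 0.0209) and smooth muscle genes (0.27, 0.0430) were wider in replicate 2 by permutation. Lung epithelial (0.04), mesenchyme (0.12), endothelial (0.08) and ribosomal protein genes (0.08) did not pass. The comparison was added after the data were seen and sets 1 pool against 1 pool, so it has no replicates of its own.

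**Figure D4:**
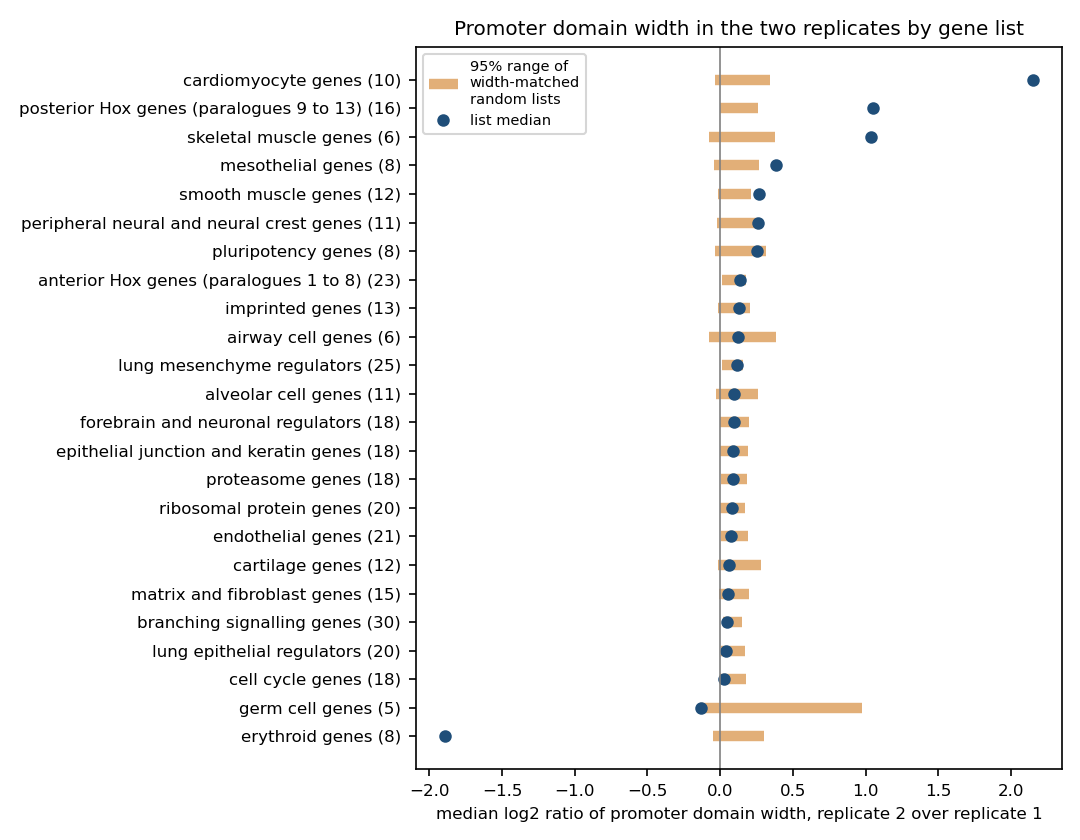
Median log2 ratio of promoter domain width in replicate 2 over replicate 1 (x axis) for 24 gene lists, with the number of genes marked in either replicate in brackets and the 95% range of width-matched random lists in orange. Cardiomyocyte genes lie at 2.15 and erythroid genes at −1.89, outside their ranges on opposite sides.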

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

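The values in this part were looked up after the main comparisons, and no test was run on them beyond their counting intervals.

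Genes for long non-coding RNAs lay outside the comparisons of coding genes and were singled out because they carried the mark. Of 7074 such genes over 5 kb from coding promoters, 633 were marked (8.95%, interval 8.31 to 9.64), with a median width of 1.17 kb. The widest, all named after their values were seen, shared a domain with a neighbouring coding gene: Gm44946 and Gm44948 in the 25.5 kb domain of Nr2f2, Sfta3-ps in the 20.2 kb domain of Nkx2-1 and 9030622O22Rik in the 14.1 kb domain of Foxa2. Carmn, a long non-coding RNA gene of smooth muscle, had 9.70 kb (8.12 kb in replicate 1 and 10.96 kb in replicate 2), Malat1 8.44 kb and Neat1 6.36 kb.

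The pooled list held 3689 peaks that the replicated list did not, and 1124 of them (30.5%) lay within 1 kb of a TSS, which singled them out. They were weak, with a median fold of 2.997 and a median width of 251 bp for all 3689. All 22739 replicated peaks were also peaks of the pooled list, and 21454 of them (94.3%) overlapped a peak in both replicates. The other 1285 had a median fold of 3.61, and 5 of these overlapped none in either replicate.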

How the results depend on the processing

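The settings with a TSS inside the peak, without peaks shared between genes, with each domain counted once, matched on CpGs and with single peaks were chosen after the data were seen, and the others before. No paired analysis was possible because the study has 1 group. Over 593 recomputed values of the main results, 457 kept their direction and side of the threshold or moved by less than their spread. Without turning, 25 lost and 22 gained a call. A further 52 turned direction, some of them also losing or gaining a call, and 37 moved. Of 1176 recomputed values of 196 named genes, 801 stayed within their spread. Except where a setting itself sets the value, as a stricter threshold does for numbers of peaks, the cause of a change was not tested. The lists hold no reads, so what depth limits cannot be measured. The median promoter fold was 15.5 for endothelial and 65.5 for ribosomal protein genes, so a stricter threshold removes the former first by construction. The numbers of marked genes lay between 11735 and 14773 over the settings run. The wider domains of lung epithelial, mesenchyme, branching, imprinted, matrix and cell cycle genes kept their direction and side of the threshold in every setting run, as did the higher marked share of lung epithelial, mesenchyme, branching, cell cycle and ribosomal protein genes and the lower one of macrophage, hepatocyte, germ cell and olfactory receptor genes against other genes. Against CpG-matched lists only the germ cell and olfactory receptor shares of these passed with the settings of the report. The lists with a higher share could not pass there, since the range of their matched lists reached 100%.

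With the stricter q threshold there were 13377 and 14815 peaks in replicates 1 and 2, with median widths of 1944 and 1969 bp, of which 99.9% and 90.7% were shared, with a rho of 0.947 for the fold. The promoter share was 97.1%, and 206 distal peaks (1.81%) were left. The CpG classes had 88.8%, 34.4% and 1.58% marked. Lists marked more often numbered 7 and less often 13, and among CpG-matched lists 2 and 9. The matrix call was lost (66.7%). Calls were gained by erythroid (6.67%), skeletal muscle (16.7%), pluripotency (7.69%) and imprinted genes (85.7%). The marked share turned to lower than other genes (53.5%) for epithelial junction (50%), alveolar (37.5%), smooth muscle (25%), endothelial (23.8%), mesothelial (20%), cartilage (23.1%), peripheral neural (21.4%), cardiomyocyte (9.09%), forebrain (0%), anterior Hox (52.2%) and posterior Hox genes (0%), of which endothelial, peripheral neural, cardiomyocyte, forebrain and posterior Hox genes passed as lower. The percentile among CpG-matched lists was past the threshold for mesenchyme regulators (99.985), pluripotency (0) and posterior Hox genes (0). It turned for epithelial junction (6.60), alveolar (29.5), smooth muscle (5.06), endothelial (0.510), mesothelial (0.055), cartilage (1.30), erythroid (13.8), peripheral neural (0.020), cardiomyocyte (13.1), skeletal muscle (7.86), forebrain (0) and anterior Hox genes (0.225), of which endothelial, mesothelial, peripheral neural, forebrain and anterior Hox genes passed as lower. Lists with wider domains numbered 8 and with narrower domains 0. Among the lists called before, smooth muscle, cardiomyocyte, skeletal muscle and pluripotency genes had under 5 marked members and were not tested for width. The endothelial (1.5) and ribosomal (1.19) width ratios lost their call, the alveolar ratio gained it (1.63) and that of proteasome genes turned (0.991).

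Counting 50% overlap of both peaks as shared left 74.4% of replicate 1 and 67.2% of replicate 2 peaks. With the pooled list the promoter share was 67.3%, the posterior Hox share passed the threshold (93.8%), the skeletal muscle width ratio lost its call (0.621), and those of mesothelial (0.987) and forebrain genes (1.17) turned. With a 500 bp window the promoter share was 70.5% and the shares of mesothelial (60%) and cardiomyocyte genes (63.6%) turned. With 2 kb it was 78.2% and imprinted genes passed (100%). With a single TSS per gene it was 62.8%, matrix (86.7%) and endothelial genes (85.7%) lost their call, and alveolar (56.2%) and mesothelial shares (60%) turned. With a TSS inside the peak 8 lists were marked less often. Matrix (86.7%), smooth muscle (91.7%) and forebrain genes (78.9%) lost their call, erythroid (33.3%), skeletal muscle (25%) and imprinted genes (92.9%) gained one, and mesothelial (60%), peripheral neural (64.3%) and cardiomyocyte genes (27.3%) turned. Of those that turned, cardiomyocyte genes passed as lower (exact test, adjusted p = 0.0338). Without shared peaks, airway (33.3%), proteasome (66.7%) and anterior Hox genes (69.6%) lost their call. The distal share with a 10 kb limit was 9.83%.

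Without a merge gap 6 lists were narrower. The endothelial width ratio (1.15) lost its call, those of airway (0.534), cartilage (0.628) and posterior Hox genes (0.504) gained it, and those of smooth muscle (0.847) and erythroid genes (0.992) turned. With a 3 kb gap smooth muscle (1.43), endothelial (1.31) and cardiomyocyte ratios (0.753) lost their call, mesothelial (0.966), forebrain (1.35) and proteasome ratios (0.999) turned, and 12 of the 20 widest domains stayed among the widest. Counting each domain once, the anterior Hox ratio lost its call (1.03) and the forebrain ratio turned (1.002). Matched on CpGs, 5 lists were narrower, the ribosomal ratio lost its call (1.23), forebrain (0.642) and posterior Hox ratios (0.4997) gained it, and the mesothelial ratio turned (0.794).

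With either replicate alone, the promoter share ranged from 64.0 to 67.7%, the distal share from 14.7 to 17.1% and the number of distal peaks from 3936 to 5062. The high, intermediate and low CpG classes ranged from 98.6 to 98.8%, 66.1 to 68.0% and 8.33 to 9.30%. The marked share ranged from 6.67 to 20% for macrophage, 21.4 to 35.7% for germ cell, 63.6 to 90.9% for cardiomyocyte and 81.2 to 100% for posterior Hox genes, which passed in replicate 2 alone. The percentile among CpG-matched lists ranged from 94.99 to 99.9 for erythroid (passed in replicate 1 alone), 14.4 to 62.0 for macrophage, 31.7 to 65.5 for peripheral neural, 98.5 to 100 for cardiomyocyte, 27.0 to 48.2 for skeletal muscle and 1.45 to 79.4 for posterior Hox genes. Lists with narrower domains numbered 0 to 4. The width ratio ranged from 1.37 to 1.73 for smooth muscle, 1.29 to 1.43 for endothelial, 0.889 to 0.939 for mesothelial, 0.801 to 1.84 for erythroid, 0.345 to 0.713 for cardiomyocyte, 0.567 to 0.918 for skeletal muscle, 1.01 to 1.17 for forebrain, 0.456 to 0.660 for pluripotency, 0.990 to 1.08 for proteasome and 0.527 to 0.791 for posterior Hox genes. The posterior Hox ratio passed as narrower in replicate 1 alone. The erythroid ratio was the higher one in replicate 1, where it passed, and the cardiomyocyte share the higher one in replicate 2.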

Other observations

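In this part the tests of the adult alpha globin genes, of shared domains and of chance and sensitivity between the replicates were chosen after the result was seen. All patterns were noticed in the data; the comparisons matched on CpGs, of unique sequence at globin genes and of further lists were added then, before their own results were seen.

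Erythroid genes were unevenly marked. The erythroid transcription factor genes Tal1 (8.14 kb), Nfe2 (3.47 kb) and Klf1 (2.12 kb) and the erythropoietin receptor gene Epor (2.96 kb) had replicated domains, as had the membrane protein genes Slc4a1 (3.14 kb) and Gypa (1.81 kb). None of the 7 globin genes listed had a peak within 1 kb of a TSS. The non-coding imprinted genes outside the tested list were marked: Kcnq1ot1 with 3.63 kb, Meg3 with 3.03 kb and H19 with 2.71 kb. Of the genes without a peak in their list, Ndn was the only imprinted one and Matn1 the only cartilage one. Klf4 (4.68 kb) and Sall4 (2.69 kb) led the marked pluripotency genes, while Nanog, Zfp42 and Dppa4 had no peak (Nanog and Zfp42 named after their values were seen).

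The first pattern is the wide domains at lung epithelial and mesenchymal regulators. Dense CpGs around these promoters were tested as the cause: against marked genes with as many CpGs within 5 kb, the smaller of the 2 median width ratios was 1.89 and both medians stayed above the 95% range. Several coding genes in one domain are excluded as the cause, since 0 of the 45 members had a domain with a promoter peak of another coding gene, against 20.6% of all marked genes. Non-coding genes were not counted, so domains shared with their promoters stay open. Sfta3-ps shared the domain of Nkx2-1 and 9030622O22Rik that of Foxa2. A single replicate as the source is also argued against, since the smallest ratio in either replicate alone was 2.55. The design names no group that would test a biological explanation; that wide domains mark the regulators of the tissue's own cell types remains a hypothesis, found and tested on the same data, and mixing of cells that differ in width was not tested.

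The second pattern is the absence of peaks at the globin genes listed. Which of these genes were active at this stage was not tested. Reads shared between near-identical copies do not account for all of it, since 100% of the 32-mers within 500 bp of the TSSs of Hba-x, Hbb-bh1 and Hbb-y were unique in the genome (all Hbb genes here were named after their values were seen). At Hbb-bs and Hbb-bt the shares were lower, 79.2% and 69.8%. For the adult alpha genes Hba-a1 and Hba-a2 the higher share was 11.96%, so lost reads may account for those 2 genes. A peak just outside the window is argued against, since 0 of the 7 genes had a pooled peak within 5 kb. For Hba-a1 and Hba-a2 this cannot decide, because lost reads could hide a nearby peak too. No biological explanation was tested, and a mark below the detection limit of the peak lists stays open.

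The third pattern is the difference of heart and blood genes between the replicates, which was tested on further lists with no shared members: 11 of 12 heart muscle genes were wider in replicate 2 (median log2 ratio 0.58, range of width-matched lists −0.02 to 0.29; permutation p = 0.00042) and 17 of 17 erythroid genes in replicate 1 (−1.34, range −0.0018 to 0.22; p = 2e-05, the smallest possible). Of 18 heart genes listed 12 entered, with ratios from −0.04 at Myl3 to 3.37 at Ankrd1. Only 8 of these 12 had a peak in replicate 1, and 10 of the 17 erythroid genes had one in replicate 2. For the rest, the 0.2 kb added stood in for a missing width. Whether the further heart list separates heart from skeletal muscle was not tested. Myl3, Tnnc1 (0.04) and Myl4 (0.07) lay below the 0.09 of all marked genes (all named after their values were seen). Chance in calling weak peaks is argued against by the medians of both lists, which lay outside their ranges. More sensitive calling in replicate 2 is argued against for the erythroid genes only, which were wider in replicate 1. It stays open for the heart genes, since matching was on width and not on fold. The first cardiomyocyte list had a median fold of 5.28, against 48.1 over all marked genes. Posterior Hox (6.09) and skeletal muscle genes (8.94) had the next lowest medians and were also wider in replicate 2. Forebrain (14.4) and endothelial genes (15.5) did not pass. For the heart genes, more sensitive calling in replicate 2 predicts the same direction. A candidate explanation of the opposite directions is that the pools held different shares of heart and blood cells, which predicted the direction of both medians. The authors' folds, read within each replicate's own list and not tested (medians at promoter peaks 28.2 in replicate 1 and 31.1 in replicate 2), went both ways at erythroid genes (15.3 and 22.3 at Gypa, 36.7 and 41.1 at Klf1, 17.7 and 20.1 at Epor, 18.8 and 19.1 at Tal1, 14.2 and 13.9 at Nfe2, 7.82 and 3.23 at Slc4a1) and were the higher ones in replicate 2 at 6 of 7 cardiomyocyte genes (5.08 and 6.96 at Nkx2-5, 4.75 and 6.61 at Actc1; the other was Myl7 with 4.09 and 3.66, named after its values were seen). Whether the explanation covers the skeletal muscle (1.04), posterior Hox (1.05), mesothelial (0.38) and smooth muscle genes (0.27), also wider in replicate 2, was not tested, the step of the collection that differed is open, and no biological difference between the pools was tested.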
